A study of Mus musculus with 10 samples.

How the data were processed

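RNA of adipocytes from the popliteal fat of C57BL/6 mice was sequenced in 10 libraries that fall into 5 groups of 2. Per the labels, mice received 1000000 colony-forming units of wild-type Listeria monocytogenes, a bacterium that lives inside host cells, under the skin of a footpad. Adipocytes were taken 24 h or 48 h later from the infected leg and from the opposite leg of infected mice, and from mice that had received PBS only. The labels describe the opposite leg once as PBS-injected and once as not injected, and give no time for the PBS mice. Per the series' design text, adipocytes were isolated by centrifugation and each condition had 2 independent biological replicates. It is not stated whether a replicate was 1 animal or a pool. Per the labels' protocols, RNA was extracted with RNeasy columns and DNase, libraries were made with a stranded TruSeq mRNA kit, and an Illumina HiSeq was used.

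The deposited values were whole-number counts of reads per gene, 1 table per library, with no normalization. STAR, featureCounts, DESeq2 and deepTools are named in the submitters' processing notes without versions, beside the builds mm10 and GRCm38. The settings of the counting, including strand and the treatment of reads that fit several genes, are not given in the sources used here. Genes of near-identical families (Saa1 and Saa2, Serpina3, guanylate-binding proteins, class I MHC, haemoglobin) are therefore uncertain where reads could be split between copies, as are genes that overlap another gene. Of 53465 gene IDs, 53360 matched the GENCODE M21 annotation of GRCm38, which gave symbols and coordinates, and 105 did not. Total counts per library ran from 10707460 to 13936501, and a count of 3 in the shallowest library equals 0.280 CPM (counts per 1000000 counts). Such floors cover counting error only.

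Genes were kept with edgeR's filterByExpr (minimum count 10), which left 13171 genes. Libraries were scaled with TMM factors. All 10 libraries entered 1 edgeR fit with 1 coefficient per group and robust quasi-likelihood dispersions (5 residual degrees of freedom, median prior degrees of freedom 6.75, common dispersion 0.0134). Each comparison was a contrast tested with edgeR's quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over the genes tested, and genes at an adjusted p under 0.05 were counted. Every adjusted p of a gene comes from this test in the main fit, unless DESeq2 or another fit is named beside it. Standard errors were taken from the fit as the fold change divided by the root of the F statistic. CPM values are given as means with SD over 2 libraries. An exact permutation test of 2 libraries against 2 cannot give a p below 0.333, so none was used for single genes.

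Before the data were examined, 34 gene lists (21 of pathways and 13 of cell types, 723 genes, 722 of them found), a panel of 33 genes, the comparisons, the tests and all alternatives except 1 were fixed. Each list with at least 3 tested members was tested with fry, a rotation test of whether its genes move on balance in 1 direction, with Benjamini-Hochberg adjustment over the 33 lists of a comparison. Fry does not compare a list with other genes. An adjusted p given with an estimated correlation comes from camera, which does compare a list with the other genes. The 2 tests therefore ask different questions. Members were counted over all genes tested and again adjusted over the list alone. The list of epithelial markers had 2 tested members and was not tested. Of the panel, Ucp1 and Cd3e fell under the count filter. Some genes stand in 2 lists: Ccl5 is in the chemokine list and the T and NK cell list, Cxcl9 in the interferon-gamma and chemokine lists, Ciita in the interferon-gamma and class II lists, Cidea in the adipocyte and thermogenic lists, and Icam1 in the NF-kappaB and preadipocyte lists. Adrb3 and Aqp7 are shared by the adipocyte and lipolysis lists, and Sdha, Sdhb, Sdhc and Sdhd by the oxidative phosphorylation and tricarboxylic acid cycle lists.

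Named genes followed a fixed rule. For the local responses at 24 h and 48 h, these were the 10 genes with the highest and the 10 with the lowest log2 fold change among genes past the threshold with an average log2 CPM of at least 1, leaving out unnamed gene models and pseudogenes. For other comparisons 5 and 5 were taken. To these were added up to 4 members of each list with the greatest change among those past the threshold, or the most expressed member where none passed, and the panel. The text gives a part of these genes, and some are not reported here. A gene named outside the rule is said to be so.

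The pipeline was tested on counts simulated from the real means and library sizes for the local response at 24 h, with 200 of 13171 genes changed. Of genes changed 1.5-fold, 26.6% were called in the true direction, of those changed 2-fold 63.8%, and of those changed 4-fold 92.5%. The real comparison called 3430 genes, and these rates depend on the share of genes changed, so they need not hold there. Of 127 calls, 3.15% were among unchanged genes, and of 126 calls by DESeq2 5.56% were. A list of 20 genes raised 1.5-fold gave a fry p of 3.52e-05, and 7.50% of 200 unchanged lists had a fry p under 0.05. Genes were simulated independently and these lists drawn at random, so this share does not cover lists whose genes vary together. With no change simulated, the comparisons gave 0 to 2 calls.

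The alternatives set beforehand were no filter, a mean CPM of at least 1, RLE factors, leaving out mitochondrially encoded, haemoglobin and skeletal muscle genes, no robust estimation, the replicate number as a block, a fit of only the libraries compared, DESeq2, leaving out each library in turn, camera with a preset (0.01) or an estimated correlation, fry for change in either direction, and a threshold of 0.01 for the overlap of the local responses. Leaving out rRNA-like transcripts was added after the data were seen. These were genes annotated as rRNA and others seen to be high in the opposite leg at 48 h. The versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.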

Results

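Adipocytes of the popliteal fat, the fat pad behind the knee, were profiled in 10 libraries. The groups were the infected leg at 24 h and at 48 h after a footpad injection of Listeria monocytogenes, the opposite leg of infected mice at 24 h and at 48 h, and mice that had received PBS, with 2 libraries each. Total counts were 13936501 and 12062914 in PBS mice, 11323347 and 10833782 in the opposite leg at 24 h, and 11464098 and 11139738 in the infected leg at 24 h. At 48 h they were 10707460 and 11830830 in the opposite leg and 12564982 and 10944472 in the infected leg. Between 18026 and 19217 genes had at least 1 count in a library, and 13171 genes were tested.

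Adipocyte transcripts were abundant in the libraries. Adipoq (adiponectin, a hormone of adipocytes; ENSMUSG00000022878, chromosome 16, 23146536 to 23158028) had a mean of 3724 ± 115 CPM in PBS mice (SD, n = 2), and Fabp4, a fatty acid carrier, had 8344 ± 429 CPM. Ptprc, the pan-leukocyte antigen CD45, had between 3.56 ± 0.129 and 7.44 ± 3.15 CPM in the 5 groups (SD, n = 2). All coordinates are of build GRCm38 with the GENCODE M21 annotation. The share of mitochondrially encoded counts was 15.9 and 14.1% in PBS mice. It was 13.0 and 11.1% in the opposite leg and 9.08 and 11.3% in the infected leg at 24 h, and 10.2 and 10.3% in the opposite leg and 5.76 and 6.65% in the infected leg at 48 h. The first principal component (50.1% of the variance) placed the libraries in the order PBS mice (45.4 and 45.0), opposite leg at 24 h (31.4 and 29.2), opposite leg at 48 h (18.1 and 15.6), infected leg at 24 h (-36.5 and -41.2) and infected leg at 48 h (-48.4 and -58.4). The second (17.4%) set the infected leg at 24 h (35.4 and 39.1) apart from that at 48 h (-26.3 and -32.1). Libraries of a group differed by more than counting noise, with a chi-square per gene of 7.23 to 16.8 and a Pearson correlation of log2 CPM across genes of 0.984 to 0.990, where genes are not independent replicates.

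The local response at 24 h was asked of the infected leg against the opposite leg of infected mice. Lcn2 (lipocalin-2, which binds bacterial iron carriers; ENSMUSG00000026822, chromosome 2, 32384633 to 32388252) rose from 2.84 ± 2.67 to 610 ± 346 CPM (SD, n = 2), a log2 fold change of 7.76 ± 0.69 (SE; edgeR adjusted p = 0.000182). The acute-phase gene Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700) rose by 6.14 ± 0.66, the cell adhesion gene Chl1 (ENSMUSG00000030077, chromosome 6, 103510586 to 103750211) by 5.92 ± 0.39 and the chemokine Ccl5 (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518) by 5.71 ± 0.72, from 2 and 7 counts in the opposite leg. Serpina3i rose by 4.81 ± 0.26, the Wnt antagonist Sfrp1 by 4.77 ± 0.18 and Acod1, which makes itaconate, by 4.65 ± 0.63. The genes that fell most included the macrophage scavenger receptor Cd163 (-3.25 ± 0.45; ENSMUSG00000008845, chromosome 6, 124304656 to 124330527), the retinol carrier Rbp7 (-3.06 ± 0.27), Chst1 (-2.89 ± 0.16) and the imprinted gene Nnat (-2.17 ± 0.34).

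Genes induced by interferons rose at 24 h. Of 35 type I interferon-stimulated genes 30 rose, 1 fell and 4 did not pass (31 and 1 adjusted over the list alone). The median log2 fold change was 1.77, and the antiviral genes Mx1 (4.61 ± 0.36), Oas3 (4.41 ± 0.32), Oasl2 (2.81 ± 0.22) and Isg15 (2.54 ± 0.16) were among them. The list had a fry adjusted p of 0.00138, and an adjusted p = 0.0755 with an estimated correlation. Of 33 interferon-gamma-inducible genes 28 rose and 5 did not pass (29 adjusted over the list alone). Gbp8 (3.39 ± 0.30), Ubd (3.14 ± 0.25) and Gbp2 (1.70 ± 0.23) rose, and the list had adjusted p = 0.00248 (adjusted p = 0.135 with an estimated correlation). Antigen presentation genes rose as well. In class I, 19 of 21 genes rose and 2 did not pass (21 adjusted over the list alone). The peptide-loading gene Tapbp was at 1.87 ± 0.15, and the immunoproteasome subunits Psmb10 and Psmb9 were at 1.86 ± 0.12 and 1.83 ± 0.13. The class I list had adjusted p = 0.000305 (adjusted p = 0.0755 with an estimated correlation). In class II, 8 of 10 rose and 2 did not pass (8 adjusted over the list alone), with H2-DMb1 at 2.90 ± 0.16, the class II transactivator Ciita at 2.70 ± 0.35 and the invariant chain Cd74 at 2.45 ± 0.17. The class II list had adjusted p = 0.00104 (adjusted p = 0.0755 with an estimated correlation). Ifit1 was 0.86 ± 0.41 (adjusted p = 0.170) and did not pass, though it was called higher with only these 4 libraries fitted (0.0159).

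Acute-phase genes rose in 17 of 22 and 5 did not pass (19 adjusted over the list alone). Hp, which binds free haemoglobin, went from 1934 ± 518 to 18065 ± 3449 CPM (SD, n = 2). The acute-phase list had adjusted p = 0.00134 (adjusted p = 0.0755 with an estimated correlation). Of 34 chemokines and cytokines 18 rose and 16 did not pass (21 adjusted over the list alone), including Cxcl9 (2.01 ± 0.25) and the B cell survival factor Tnfsf13b (2.68 ± 0.19). As a list, chemokines had adjusted p = 0.0135 (adjusted p = 0.363 with an estimated correlation). NF-kappaB targets rose in 16 of 31 and 15 did not pass (16 adjusted over the list alone), including the adhesion molecule Vcam1 (2.19 ± 0.40) and Tnfaip2 (1.97 ± 0.17). As a list, NF-kappaB targets had adjusted p = 0.0242 (adjusted p = 0.387 with an estimated correlation). Tnf itself was 0.30 and did not pass. The calls of both lists were lost without infected-leg replicate 2 (0.0566 for chemokines, 0.120 for NF-kappaB targets) and without opposite-leg replicate 1 (0.0663 and 0.0882).

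Several lists of adipocyte and fat metabolism genes were called lower at 24 h. Of 23 adipocyte identity genes 18 fell and 5 did not pass (18 lower and 1 higher adjusted over the list alone). The activin receptor Acvr1c (-1.65 ± 0.12), Nrg4 (-1.60 ± 0.11) and Fabp4 (-0.71 ± 0.14) were among them. This list had an adjusted p of 1.83e-05 and was the 1 list of 33 whose call held in the camera test with an estimated correlation (adjusted p = 0.0169). Adipoq was at -0.52 ± 0.14 (adjusted p = 0.0192), a call lost without infected-leg replicate 1 (0.0717) or 2 (0.0855) and without opposite-leg replicate 1 (0.0528) or 2 (0.0936), and when only these 4 libraries were fitted (0.0602). Of 20 lipolysis genes 8 fell and 12 did not pass (9 adjusted over the list alone). The lowest were Prkar2b, a regulatory subunit of protein kinase A (-2.03 ± 0.12; ENSMUSG00000002997, chromosome 12, 31958476 to 32061296), and Pde3b, which degrades cyclic AMP (-2.02 ± 0.13). The lipolysis list had adjusted p = 0.00134 (adjusted p = 0.121 with an estimated correlation). It holds lipases and regulators such as Prkar2b and Pde3b, so its direction does not give that of lipolysis itself. The hormone-sensitive lipase Lipe fell by 0.67 on the log2 scale and Pnpla2, the first lipase of the pathway, was at -0.15 and did not pass. Thermogenic genes fell in 5 of 11 and 6 did not pass (6 adjusted over the list alone), including the potassium channel Kcnk3 (-1.89 ± 0.16) and Cidea (-1.58 ± 0.29). The thermogenic list had adjusted p = 0.00875 (adjusted p = 0.383 with an estimated correlation). In fatty acid oxidation 8 of 22 fell, 1 rose and 13 did not pass (8 lower and 2 higher adjusted over the list alone). Ppara (-2.06 ± 0.32) and Acsl1 (-1.30 ± 0.15) were lower and Cpt1a (1.02 ± 0.19), the entry step into mitochondria, was higher. The oxidation list had adjusted p = 0.00395 (adjusted p = 0.387 with an estimated correlation).

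The lists of glycolysis and cholesterol synthesis were called higher at 24 h. In glycolysis 6 of 19 genes rose, 2 fell and 11 did not pass (7 and 2 adjusted over the list alone), with Pfkp higher (1.32 ± 0.12) and its muscle paralog Pfkm lower (-1.17). The glycolysis list had adjusted p = 0.00395 (adjusted p = 0.383 with an estimated correlation). In cholesterol synthesis 9 of 21 rose, 1 fell and 11 did not pass (12 and 1 adjusted over the list alone), among them Mvd (1.20 ± 0.25) and Cyp51 (0.84 ± 0.16). The cholesterol list had adjusted p = 0.0149 (adjusted p = 0.383 with an estimated correlation). That call was lost without infected-leg replicate 1 (0.0689) and without opposite-leg replicate 2 (0.0863). Lipogenesis had 8 of 23 lower, 1 higher and 14 that did not pass (adjusted p = 0.0780), with the triglyceride-forming enzyme Dgat1 at -1.84 ± 0.14. Nuclear-encoded oxidative phosphorylation had 1 of 65 lower and 64 that did not pass (adjusted p = 0.909), mitochondrially encoded mRNAs 13 of 13 that did not pass (median -0.14, adjusted p = 0.525), and the tricarboxylic acid cycle 1 of 22 lower (adjusted p = 0.198). Collagens (3 of 26 higher, 6 lower; adjusted p = 0.449), endoplasmic reticulum stress (6 of 18 higher, 2 lower; 0.351), immediate-early genes (4 of 24 higher, 3 lower; 0.451) and the cell cycle (1 of 17 higher, 2 lower; 0.333) did not pass as lists. Adjusted over the list alone, lipogenesis had 10 lower and 1 higher, collagens had 5 higher and 10 lower, oxidative phosphorylation lost its 1 gene, and the other counts in these lists were as over all genes.

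Markers of other cells moved in both directions at 24 h. Of 19 monocyte and macrophage markers 3 rose and 4 fell (adjusted p = 0.482), with Mrc1 at -1.79 ± 0.30 and Ptprc at 0.02. Of 14 blood endothelial markers 4 fell and 10 did not pass (adjusted p = 0.0759), with the VEGF receptor Kdr at -1.52 ± 0.22. Of 14 preadipocyte and fibroblast markers 6 fell, 1 rose (Ly6a, which interferon also induces, 2.46 ± 0.17) and 7 did not pass (adjusted p = 0.134). Of 5 T and NK cell markers 1 rose, the chemokine Ccl5, which the chemokine list also holds (adjusted p = 0.0135, and adjusted p = 0.383 with an estimated correlation). Of 4 dendritic and mast cell markers 3 fell, the lectin Clec10a (-1.42), the receptor Kit (-1.09) and the transcription factor Zbtb46 (-0.67). The calls of Clec10a and Zbtb46 were lost without infected-leg replicate 1 (0.134 and 0.103) or opposite-leg replicate 1 (0.0538 and 0.1015), and that of Clec10a also without infected-leg replicate 2 (0.0517) or opposite-leg replicate 2 (0.1004). Zbtb46 also lost it with only these 4 libraries fitted (0.0752) and with DESeq2 (0.0962). The dendritic and mast cell list had adjusted p = 0.0149 (adjusted p = 0.582 with an estimated correlation). The list's call was lost without infected-leg replicate 1 (0.122) and without opposite-leg replicate 2 (0.0863). Adjusted over the list alone, 3 monocyte and macrophage markers were higher and 5 lower, 6 endothelial markers were lower, 9 preadipocyte markers were lower and 1 higher, and the T cell and dendritic counts were as over all genes. Neutrophil (adjusted p = 0.598), pericyte (0.159), lymphatic (0.690), red blood cell (0.639), skeletal muscle (0.372), nerve (0.482) and B cell (0.351; median -0.24 but a test upward) markers did not pass as lists. Opposite-leg replicate 2 at 24 h stood apart from replicate 1 in stromal and endothelial genes that were picked after their values were seen. Pdgfra was at 16.3 against 5.54 CPM, Dcn at 157 against 81.2 CPM and Plvap at 42.9 against 15.9 CPM.

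In all, 3430 genes passed at 24 h, 1652 higher and 1778 lower, and 1267 of them changed at least 2-fold (581 and 686). Fry called 15 of 33 lists, 10 up and 5 down. Without opposite-leg replicate 2 the number of genes was 2182. With only these 4 libraries fitted, 1384 were higher and 1067 lower, with RLE factors 1778 and 1615, and over all alternatives the share of higher genes ran from 46.1 to 56.5%. Of 122 named genes called, 85 held in every alternative, which includes each left-out library.

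**Figure D1:**
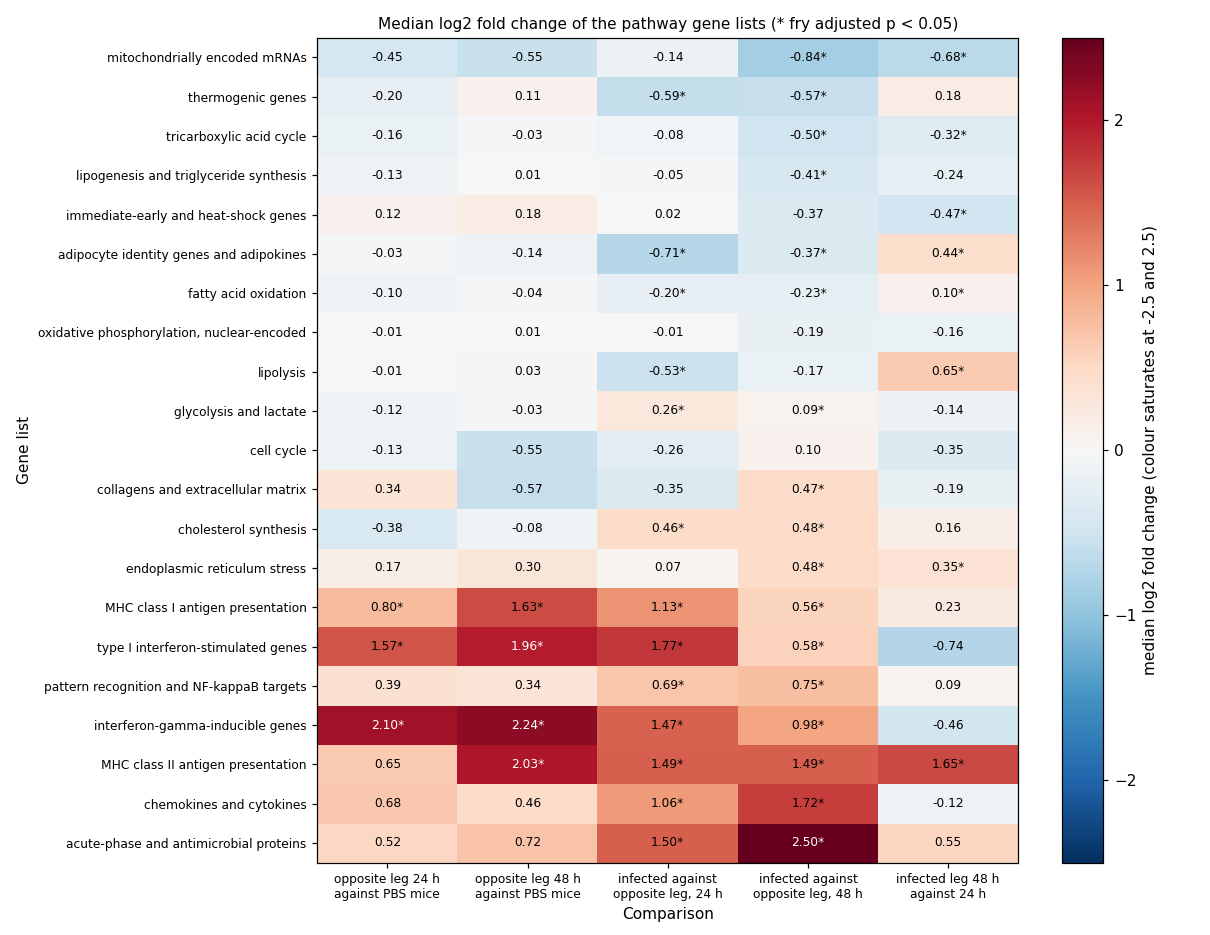
Median log2 fold change of each of 21 pathway lists (vertical axis) in 5 comparisons (horizontal axis), where colour gives the median, saturating at 2.5 in either direction, and an asterisk a fry adjusted p under 0.05. Interferon, antigen presentation and acute-phase lists had positive medians in the infected leg at both times, and adipocyte identity genes had negative ones (-0.71 at 24 h and -0.37 at 48 h against the opposite leg).

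The same question was asked at 48 h. Lcn2 stood at 2513 ± 760 CPM in the infected leg against 2.56 ± 0.702 CPM in the opposite leg (SD, n = 2), a log2 fold change of 9.93 ± 0.74 (SE; edgeR adjusted p = 0.000120). Saa3 rose by 9.25 ± 0.75, Chl1 by 8.54 ± 0.38, from 5 and 3 counts in the opposite leg, and Ccl5 by 6.08 ± 0.62. Tmem176a rose by 4.51 ± 0.48, the monocyte chemokine Ccl8 by 4.15 ± 0.48, the cytokine Lif by 4.15 ± 0.51, Acod1 by 4.15 ± 0.70 and Nos2, which makes nitric oxide, by 2.95 ± 0.50. Lower genes included Cd163, with 2 and 1 counts in the infected leg against 58 and 35 in the opposite leg, Retnla, a product of alternatively activated macrophages (-4.48 ± 0.55), Nnat (-3.43 ± 0.36), the macrophage lectin Mgl2 (-3.36 ± 0.59), the endothelial gene Btnl9 (-3.35 ± 0.29) and Thrsp, which promotes fatty acid synthesis (-3.06 ± 0.21).

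Defence lists were higher again at 48 h. Acute-phase genes rose in 18 of 22 and 4 did not pass (19 higher and 1 lower adjusted over the list alone), with Hp, chosen here after its values were seen, at 26246 ± 4831 CPM (SD, n = 2). The list had adjusted p = 0.00171 (adjusted p = 0.116 with an estimated correlation). Class II genes rose in 8 of 10 (9 adjusted over the list alone), among them Cd74 (2.42 ± 0.16; ENSMUSG00000024610, chromosome 18, 60803848 to 60812652), H2-Aa (1.87 ± 0.15) and H2-Eb1 (1.70 ± 0.14). The class II list had adjusted p = 0.00261 (adjusted p = 0.150 with an estimated correlation). Class I genes rose in 13 of 21 and 8 did not pass (16 adjusted over the list alone; median 0.56), with H2-Q7 at 0.92. The class I list had adjusted p = 0.00673 (adjusted p = 0.334 with an estimated correlation). Of the interferon-gamma-inducible genes 22 of 33 rose, 1 fell and 10 did not pass (22 and 1 adjusted over the list alone), with Ubd at 3.61 ± 0.25, while Gbp2 was at 0.11 and did not pass. The interferon-gamma list had adjusted p = 0.0222 (adjusted p = 0.334 with an estimated correlation). Of type I interferon-stimulated genes 17 of 35 rose, 2 fell and 16 did not pass (18 and 2 adjusted over the list alone), with Oas3 at 4.10 ± 0.29 and Oas2 at 2.90 ± 0.26 but Ifit1 at -2.41 ± 0.43. The type I list had adjusted p = 0.0324 (adjusted p = 0.362 with an estimated correlation). Chemokines and cytokines rose in 18 of 34 (21 adjusted over the list alone; median 1.72; adjusted p = 0.0164, and adjusted p = 0.334 with an estimated correlation). NF-kappaB targets rose in 16 of 31 (16 adjusted over the list alone; adjusted p = 0.0222, and adjusted p = 0.334 with an estimated correlation), with Vcam1 at 3.69 ± 0.42 and Tnfaip2 at 2.56 ± 0.18.

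The lists of the tricarboxylic acid cycle, mitochondrially encoded mRNAs and lipogenesis were called lower at 48 h. In the tricarboxylic acid cycle 16 of 22 genes fell and 6 did not pass (19 adjusted over the list alone), with the pyruvate carboxylase Pcx (-1.12 ± 0.16) and Idh3b (-0.83 ± 0.11). The tricarboxylic acid cycle list had adjusted p = 0.00527 (adjusted p = 0.334 with an estimated correlation). Mitochondrially encoded mRNAs fell in 6 of 13 and 7 did not pass (7 adjusted over the list alone; median -0.84), including mt-Cytb (-1.04 ± 0.17) and mt-Nd4 (-0.92 ± 0.16). The mitochondrial list had adjusted p = 0.0206 (adjusted p = 0.334 with an estimated correlation). Nuclear-encoded oxidative phosphorylation had 23 of 65 lower, 1 higher and 41 that did not pass (28 lower and 2 higher adjusted over the list alone; adjusted p = 0.110). Lipogenesis fell in 10 of 23, rose in 1 and did not pass in 12 (10 and 1 adjusted over the list alone), with Thrsp, the elongase Elovl6 (-1.87 ± 0.26) and the fatty acid synthase Fasn (-1.22 ± 0.23) lower. The lipogenesis list had adjusted p = 0.0206 (adjusted p = 0.334 with an estimated correlation). Fatty acid oxidation had 9 of 22 lower, 2 higher and 11 that did not pass (9 and 2 adjusted over the list alone; adjusted p = 0.0198, and adjusted p = 0.421 with an estimated correlation), with Hadh at -0.88 ± 0.11 and Cpt1a at 1.42 ± 0.20. Thermogenic genes had 5 of 11 lower, 1 higher and 5 that did not pass (5 and 1 adjusted over the list alone; adjusted p = 0.0164, and adjusted p = 0.334 with an estimated correlation), including Cidea (-2.82 ± 0.38), the thyroid hormone activator Dio2 (-1.79 ± 0.37) and Cox8b (-1.36 ± 0.23).

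Of the adipocyte identity genes 10 of 23 fell, 1 rose and 12 did not pass (11 and 2 adjusted over the list alone), with the retinol carrier Rbp4 at -1.41 ± 0.13 and Adipoq at -0.81 ± 0.14, while Fabp4 (0.39), Plin1 (-0.14) and Pparg (0.33) did not pass. The list had an adjusted p of 0.000245 (adjusted p = 0.116 with an estimated correlation). With no filter Fabp4 (0.0288) and Pparg (0.0335) were called higher, as was Fabp4 with DESeq2 (0.00919). Lipolysis had 4 of 20 lower, 2 higher and 14 that did not pass (5 and 2 adjusted over the list alone; adjusted p = 0.412). Endoplasmic reticulum stress genes rose in 9 of 18, fell in 1 and did not pass in 8 (10 and 1 adjusted over the list alone). These included Sdf2l1 (2.66 ± 0.27), Creld2 (1.36 ± 0.17) and the disulfide isomerase Pdia6 (1.13 ± 0.14). The stress list had adjusted p = 0.0206 (adjusted p = 0.362 with an estimated correlation). Collagens and matrix genes rose in 11 of 26, fell in 1 and did not pass in 14 (12 and 1 adjusted over the list alone). Col1a1 was at 2.73 ± 0.32 and the proteoglycan Bgn at 2.57 ± 0.36. The matrix list had adjusted p = 0.0449 (adjusted p = 0.421 with an estimated correlation). In the opposite leg at 48 h this list had a median of -0.573 against PBS mice, with 5 of 26 genes lower (fry adjusted p = 0.116). It was not called in the infected leg at 48 h against PBS mice, so a lower opposite leg may hold part of this contrast. Cholesterol synthesis rose in 7 of 21 and fell in 1 (12 and 1 adjusted over the list alone; adjusted p = 0.0206, and adjusted p = 0.334 with an estimated correlation), with Hmgcs1 at 0.93 ± 0.15. Glycolysis rose in 5 of 19 and fell in 2 (6 and 3 adjusted over the list alone; adjusted p = 0.0439, and adjusted p = 0.648 with an estimated correlation), with the myeloid hexokinase Hk3 at 2.40 and Pfkm at -1.08. Immediate-early genes (3 of 24 higher, 9 lower; 4 and 11 adjusted over the list alone; adjusted p = 0.0988) and the cell cycle (2 of 17 lower, also over the list alone; 0.408; median 0.10 but a test downward) did not pass as lists.

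Blood endothelial markers fell in 8 of 14 and 6 did not pass at 48 h (10 adjusted over the list alone; median -1.26), with Kdr at -1.93 ± 0.23 and Ptprb at -1.62 ± 0.25. The endothelial list had adjusted p = 0.0319 (adjusted p = 0.334 with an estimated correlation). Of 8 neutrophil markers 4 rose, 1 fell and 3 did not pass (6 and 1 adjusted over the list alone), with Il1r2 at 3.45 ± 0.47 and Csf3r at 3.13 ± 0.48. The neutrophil list had adjusted p = 0.0222 (adjusted p = 0.334 with an estimated correlation). S100a8, an abundant neutrophil transcript, was at 3.31 ± 2.53 CPM in the infected leg (SD, n = 2). Monocyte and macrophage markers had 5 of 19 higher, 2 lower and 12 that did not pass (6 and 2 adjusted over the list alone; adjusted p = 0.510), with Ly6c2 at 3.59 ± 0.60 and Fcgr1 at 2.48 higher, Cd163 lower, and Ptprc at 1.06 and not passed. Ptprc was called higher with no filter (0.000649) and with only these 4 libraries fitted (0.0416). Of 5 T and NK cell markers 1 rose, again Ccl5 (1 adjusted over the list alone; adjusted p = 0.0198, and adjusted p = 0.334 with an estimated correlation). The preadipocyte list (2 of 14 higher, 2 lower, and the same counts adjusted over the list alone; adjusted p = 0.810) had a median of -0.30, a mean of 0.03 and a test upward. Pericyte (adjusted p = 0.242), B cell (0.242), dendritic and mast cell (0.814; median -0.02 but a test upward), lymphatic (0.814), red blood cell (0.133), skeletal muscle (0.814) and nerve (0.242; mean -0.15 but a test upward) markers did not pass as lists. The mitochondrial share of counts was lower in the infected leg, as given above.

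At 48 h 3148 genes passed, 1571 higher and 1577 lower, with 1212 changed at least 2-fold (600 and 612), and fry called 20 of 33 lists, 13 up and 7 down, none of which held in the camera test with an estimated correlation. The number of genes was 1651 without infected-leg replicate 2, 1610 without opposite-leg replicate 1 and 1648 without opposite-leg replicate 2, and the number of lists was 12 and 6 without infected-leg replicates 1 and 2 and 9 and 6 without opposite-leg replicates 1 and 2. The share of higher genes ran from 48.9 to 56.3% over the alternatives. The acute-phase, adipocyte identity, class I, class II and tricarboxylic acid cycle lists held whichever library was left out. Of the other 15, without infected-leg replicate 1 the lost lists had adjusted p = 0.0622 to 0.163, without infected-leg replicate 2 0.0652 to 0.107, without opposite-leg replicate 1 0.0600 to 0.219 and without opposite-leg replicate 2 0.0776 to 0.184. Endoplasmic reticulum stress, glycolysis, blood endothelium, mitochondrially encoded mRNAs and type I interferon-stimulated genes lost their calls in each of these cases. Chemokines lost theirs in the last case alone, and the collagens in all but the third.

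The local responses at 24 h and 48 h share no library, but both come from 1 fit with the same estimates of spread. Genes with little spread or high counts are likelier to be called at both times. The numbers due by independence are therefore a low benchmark. Genes higher at both times numbered 763, where 197 would be shared by independent sets of this size, and genes lower at both times 687, against 213. A further 59 genes passed in opposite directions. Among those was the collagen gene Col6a3 (-1.08 ± 0.13 at 24 h and 0.78 at 48 h). Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.592. At a threshold of 0.01 the shared sets held 399 and 262 genes, where 60.7 and 48.3 were due by independence.

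The opposite leg was compared with PBS mice to see how adipocytes away from the infected foot differed. At 24 h the 3 lists called held interferon-induced and class I genes. The guanylate-binding protein Gbp10 (ENSMUSG00000105096, chromosome 5, 105215699 to 105239533) rose from 4.75 ± 0.408 to 117 ± 41.1 CPM (SD, n = 2), a log2 fold change of 4.62 ± 0.29 (SE; edgeR adjusted p = 5.89e-05). Gbp2 rose by 2.15 ± 0.23, Oasl2 by 2.17 ± 0.23, Ifi44 by 2.07 ± 0.23, Psmb9 by 1.88 ± 0.13, Ly6a by 1.88 ± 0.17, the peptide transporter Tap1 by 1.86 ± 0.14 and Isg15 by 1.74 ± 0.16. Type I interferon-stimulated genes rose in 24 of 35 and 11 did not pass (35 adjusted over the list alone; median 1.57; adjusted p = 0.00700, and adjusted p = 0.0192 with an estimated correlation). Interferon-gamma-inducible genes rose in 26 of 33 and 7 did not pass (30 adjusted over the list alone; median 2.10; adjusted p = 0.00825, and adjusted p = 0.0192 with an estimated correlation), a call lost without PBS replicate 1 (0.0738). Class I genes rose in 14 of 21 and 7 did not pass (18 adjusted over the list alone; median 0.80; adjusted p = 0.00474, and adjusted p = 0.0192 with an estimated correlation).

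Other groups gave no list call in the opposite leg at 24 h. Class II genes rose in 3 of 10 (5 adjusted over the list alone; adjusted p = 0.125), with Cd74 at 0.21 and H2-Aa at 0.21, neither passed. Acute-phase genes rose in 1 of 22 (5 higher and 2 lower adjusted over the list alone), and Lcn2 was at 1.60 ± 1.01 and Saa3 at 0.40, neither passed. In the main fit no chemokine or cytokine passed over all genes tested, and 7 of 34 rose adjusted over the list alone. Among the named ones, DESeq2 called Ccl2, Cxcl9, Cxcl10 and Il6 higher (adjusted p = 0.000622 to 0.00168). Ccl2, Cxcl9 and Cxcl10 were also called higher by edgeR with no filter. Adipoq was at -0.12 and did not pass. Preadipocyte markers had 1 of 14 higher (5 adjusted over the list alone; median 0.95; adjusted p = 0.125), and replicate 2 of this group held the higher stromal counts given above. In all 213 genes passed, 187 higher and 26 lower, and fry called 3 of 33 lists. The number of genes was 70 without PBS replicate 1, 432 without opposite-leg replicate 1, where 6 lists were called, and 97 without opposite-leg replicate 2, and it was 738 with no filter and 359 with DESeq2.

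By 48 h the opposite leg differed from PBS mice in more of these genes. Gbp10 rose from 4.75 ± 0.408 to 285 ± 57.7 CPM (SD, n = 2), a log2 fold change of 5.90 ± 0.30 (SE; edgeR adjusted p = 2.06e-06). Gbp8 rose by 6.09 ± 0.47, from 4 and 5 counts in PBS mice. Ciita, with 5 and 2 counts in PBS mice and 191 and 332 in the opposite leg, was higher too. The class II genes H2-DMa (4.52 ± 0.19), H2-DMb1 (4.38 ± 0.18), H2-Ab1 (2.84 ± 0.18), Cd74 (2.08 ± 0.16) and H2-Aa (1.93 ± 0.16) were higher. So were Mx1 (3.26 ± 0.44), the nucleic acid sensor Zbp1 (2.73 ± 0.20), the complement gene C4b (2.26 ± 0.21) and B2m, the light chain of class I (1.01 ± 0.16). Lower genes included Ttc16 (-2.86 ± 0.34), the deubiquitinase Yod1 (-2.37 ± 0.17), Nectin1 (-2.27 ± 0.34) and the muscle actin Acta1 (-1.49 ± 0.22). All 21 class I genes rose (21 adjusted over the list alone; median 1.63; adjusted p = 0.000147, and adjusted p = 0.00762 with an estimated correlation). Of the class II genes 7 of 10 rose (7 adjusted over the list alone; median 2.03; adjusted p = 0.000797, and adjusted p = 0.0174 with an estimated correlation). Of the interferon-gamma-inducible genes 28 of 33 rose (31 adjusted over the list alone; median 2.24; adjusted p = 0.00219, and adjusted p = 0.0238 with an estimated correlation). Of the type I interferon-stimulated genes 33 of 35 rose (35 adjusted over the list alone; median 1.96; adjusted p = 0.00107, and adjusted p = 0.0202 with an estimated correlation). These 4 list calls held whichever library was left out.

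Acute-phase genes rose in 6 of 22 in the opposite leg at 48 h (7 adjusted over the list alone; median 0.72; adjusted p = 0.0756), with the copper carrier Cp at 1.08 ± 0.14, while Lcn2 (1.48 ± 1.03) and Saa3 (-0.12) did not pass. Lcn2 was called higher when only these 4 libraries were fitted (1.49, edgeR adjusted p = 0.0237). Chemokines rose in 9 of 34 and fell in 1 (11 and 1 adjusted over the list alone; adjusted p = 0.220), and NF-kappaB targets rose in 11 of 31 (13 adjusted over the list alone; adjusted p = 0.176). Adipocyte identity genes fell in 2 of 23 (2 lower and 1 higher adjusted over the list alone; adjusted p = 0.0756), with Adipoq at 0.14, Fabp4 at -0.21 and Lipe at 0.04, none passed. Collagens fell in 5 of 26 (7 adjusted over the list alone; adjusted p = 0.116) and blood endothelial markers in 2 of 14 (8 adjusted over the list alone; median -0.75; adjusted p = 0.187). Ptprc was at -0.23 and did not pass. The opposite leg at 48 h also held the highest share of rRNA-like transcripts, 0.693 and 0.599% against 0.271 to 0.532% in the other libraries, among them the leucyl-tRNA synthetase gene Lars2, chosen after its values were seen, at 1181 ± 143 CPM against 229 ± 133 CPM in PBS mice (SD, n = 2). Part of this set was picked for being high in these libraries, so that ranking follows in part from the choice. In all 925 genes passed, 575 higher and 350 lower, and fry called 4 of 33 lists. The number of genes was 325 and 432 without PBS replicates 1 and 2, 510 and 340 without opposite-leg replicates 1 and 2, 1608 with no filter and 1749 when only these 4 libraries were fitted.

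Both opposite-leg comparisons used the same PBS libraries. Of the genes tested, 170 were higher at both times, where independent lists of this size would share 8.16, and 10 were lower at both, where 0.691 would be shared. For a benchmark, all libraries, PBS included, were simulated from gene means over all groups with independent noise. Such unchanged groups had 0.05 calls in both on average over 20 simulations. The real PBS libraries were not used there, so any oddity of theirs is not covered. The log2 fold changes had a correlation across genes of 0.556 against 0.475 simulated, and a covariance of 0.151 against 0.0421 simulated, a difference of 0.109. With 2 control libraries the controls were not split, so part of the excess may come from the shared controls.

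Set against PBS mice, the infected leg at 24 h differed in defence and in fat metabolism genes. Lcn2 was higher by 9.36 ± 0.77 on the log2 scale (SE, n = 2 per group; edgeR adjusted p = 7.36e-05), Gbp10 by 7.23 ± 0.31, Mx1 by 6.25 ± 0.41, Isg15 by 4.27 ± 0.17 and Ifit1 (ENSMUSG00000034459, chromosome 19, 34640871 to 34650009) by 2.48 ± 0.43. The lipoprotein lipase Lpl fell from 10291 ± 164 to 2476 ± 241 CPM (SD, n = 2; log2 fold change -2.06 ± 0.14). Dgat1 (-2.25 ± 0.14), Prkar2b (-2.04) and the insulin-responsive glucose carrier Slc2a4 (-1.58 ± 0.12) fell as well. Type I interferon-stimulated genes rose in 34 of 35 (median 3.34; adjusted p = 5.6e-05), interferon-gamma-inducible genes in 32 of 33 (median 3.86; adjusted p = 0.000311) and class I genes in 21 of 21 (adjusted p = 3.23e-05). Adipocyte identity genes fell in 17 of 23 (median -0.83; adjusted p = 1.26e-05). These 4 lists held with an estimated correlation, with adjusted p = 0.0224, 0.0460, 0.0224 and 0.0224. The acute-phase (18 of 22 higher; adjusted p = 0.000669) and class II (8 of 10 higher; 0.000312) lists each had an adjusted p = 0.0580 with an estimated correlation. Adjusted over the list alone, 34 type I, 33 interferon-gamma, 21 class I and 9 class II genes were higher, 18 adipocyte genes were lower, and 19 acute-phase genes were higher and 1 lower.

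Chemokines rose in 22 of 34 (adjusted p = 0.00361, and adjusted p = 0.249 with an estimated correlation) in the infected leg at 24 h against PBS mice. All 5 T and NK cell markers rose (adjusted p = 0.00168, and adjusted p = 0.249 with an estimated correlation) and NF-kappaB targets rose in 19 of 31 (0.00592, and adjusted p = 0.295 with an estimated correlation). Of the T and NK cell markers, Klrk1 lost its call with DESeq2 (0.0923), and DESeq2 gave Trac no adjusted p. Lipolysis fell in 10 of 20 and rose in 1 (adjusted p = 0.000686, and adjusted p = 0.140 with an estimated correlation). Fatty acid oxidation fell in 13 of 22 and rose in 1 (adjusted p = 0.000884, and adjusted p = 0.295 with an estimated correlation) and thermogenic genes fell in 6 of 11 (0.00349, and adjusted p = 0.295 with an estimated correlation). Adjusted over the list alone, 26 chemokines, 5 T and NK cell markers and 20 NF-kappaB targets were higher, and 11 lipolysis, 14 oxidation and 6 thermogenic genes were lower. The lists of glycolysis (4 of 19 higher, 3 lower), lipogenesis (8 of 23 lower, 2 higher), mitochondrially encoded mRNAs (5 of 13 lower) and the tricarboxylic acid cycle (5 of 22 lower) also passed (adjusted p = 0.0173, 0.0191, 0.0409 and 0.0202), and had adjusted p = 0.859, 0.573, 0.797 and 0.859 with an estimated correlation. Over the list alone, glycolysis had 4 higher and 3 lower, lipogenesis 9 lower and 2 higher, mitochondrially encoded mRNAs 7 lower and the tricarboxylic acid cycle 3 lower. Those calls were lost for glycolysis without PBS replicate 2 (0.0903) and for lipogenesis without infected-leg replicate 2 (0.101) or PBS replicate 1 (0.0877). They were lost for mitochondrial mRNAs without infected-leg replicate 1 (0.145) or 2 (0.101) or PBS replicate 1 (0.0783), and for the tricarboxylic acid cycle without infected-leg replicate 2 (0.0870) or PBS replicate 1 (0.102). In all 4179 genes passed, 2083 higher and 2096 lower, with 2687 and 2778 without PBS replicates 1 and 2, and 16 lists were called, 9 up and 7 down. The share of higher genes ran from 48.9 to 55.6% over the alternatives.

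At 48 h the infected leg differed from PBS mice in 4475 genes, 2234 higher and 2241 lower. Lcn2 was higher by 11.40 ± 0.81 (SE, n = 2 per group; edgeR adjusted p = 4.07e-05), Saa3 by 9.13 ± 0.74, Gbp8 by 8.58 ± 0.42, Ly6a by 6.04 ± 0.20, H2-DMa by 5.94 ± 0.19, Cd74 by 4.49 ± 0.18 and the class I gene H2-T23 by 4.23 ± 0.16. Retnla (-5.96 ± 0.50), Thrsp (-3.02 ± 0.21), Ptprb (-2.71 ± 0.24), Kdr (-2.64 ± 0.23) and Scd1, the main fatty acid desaturase (-1.37 ± 0.17), fell. Class II genes rose in 9 of 10 (median 4.07; adjusted p = 5.88e-05), class I genes in 21 of 21 (median 2.14; 4.05e-05) and type I interferon-stimulated genes in 31 of 35 (median 2.01; 0.000188). Interferon-gamma-inducible genes rose in 32 of 33 (median 3.21; adjusted p = 0.000430) and acute-phase genes in 20 of 22 (median 2.52; 0.000188), while adipocyte identity genes fell in 11 of 23 and rose in 1 (median -0.27; 4.91e-05). These 6 lists held with an estimated correlation, with adjusted p = 0.0234, 0.0234, 0.0467, 0.0467, 0.0442 and 0.0467. When adjusted over the list alone, 10 class II, 21 class I, 33 type I, 32 interferon-gamma and 20 acute-phase genes were higher, and 12 adipocyte genes were lower and 1 higher.

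Blood endothelial markers fell in 12 of 14 (13 adjusted over the list alone; median -1.97; adjusted p = 0.00593, and adjusted p = 0.276 with an estimated correlation) in the infected leg at 48 h against PBS mice. Pericyte and smooth muscle markers fell in 5 of 9 with 2 higher (adjusted p = 0.0150, and adjusted p = 0.370 with an estimated correlation). The tricarboxylic acid cycle fell in 18 of 22 (0.00181, and adjusted p = 0.327 with an estimated correlation) and mitochondrially encoded mRNAs in 9 of 13 (0.00338, and adjusted p = 0.276 with an estimated correlation), beside the lower mitochondrial share of counts. Chemokines rose in 25 of 34 (0.00357, and adjusted p = 0.256 with an estimated correlation) and NF-kappaB targets in 21 of 31 (0.00419, and adjusted p = 0.276 with an estimated correlation). Endoplasmic reticulum stress genes rose in 11 of 18 with 2 lower (0.00419, and adjusted p = 0.343 with an estimated correlation) and T and NK cell markers in 3 of 5 (0.00218, and adjusted p = 0.276 with an estimated correlation). Of the latter, Klrk1 lost its call with DESeq2 (0.0658). Neutrophil markers rose in 6 of 8 with 1 lower, lipogenesis fell in 10 of 23 with 3 higher, the cell cycle fell in 4 of 17, fatty acid oxidation in 7 of 22 with 1 higher and thermogenic genes in 5 of 11 with 1 higher. Those 5 lists had adjusted p = 0.0203, 0.0185, 0.0483, 0.00652 and 0.00403, and adjusted p = 0.445, 0.445, 0.623, 0.506 and 0.307 with an estimated correlation. Adjusted over the list alone, 25 chemokines, 22 NF-kappaB targets and 3 T and NK cell markers were higher, and 18 tricarboxylic acid cycle and 10 mitochondrially encoded genes were lower. Pericytes had 6 lower and 2 higher in that count, stress genes 12 higher and 3 lower, neutrophils 6 and 1, lipogenesis 11 lower and 3 higher, oxidation 9 and 1, thermogenic genes 6 and 1, and the cell cycle 4 lower. Calls were lost for neutrophils without PBS replicate 1 (0.0932) or 2 (0.0817) and for pericytes without infected-leg replicate 1 (0.0782) or 2 (0.0964). The lipogenesis call was lost without infected-leg replicate 1 (0.0610) or 2 (0.1004) or PBS replicate 1 (0.0746). The cell cycle call was lost without infected-leg replicate 1 (0.151) or 2 (0.0701) or PBS replicate 2 (0.106). With RLE factors the cell cycle lost its call (0.0519) and cholesterol synthesis, not called otherwise, passed (0.0432). Monocyte and macrophage markers had 4 of 19 higher and 4 lower (5 and 4 adjusted over the list alone; adjusted p = 0.833), and glycolysis (5 of 19 higher, 4 lower; 5 and 5 adjusted over the list alone) had a median of -0.13 but a mean of 0.13 and a test upward (0.131). The number of genes was 2877 without infected-leg replicate 2, 2908 without PBS replicate 1 and 2963 without PBS replicate 2, and 19 lists were called, 10 up and 9 down. Between 49.1 and 54.5% of the called genes were higher over the alternatives.

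**Figure D2:**
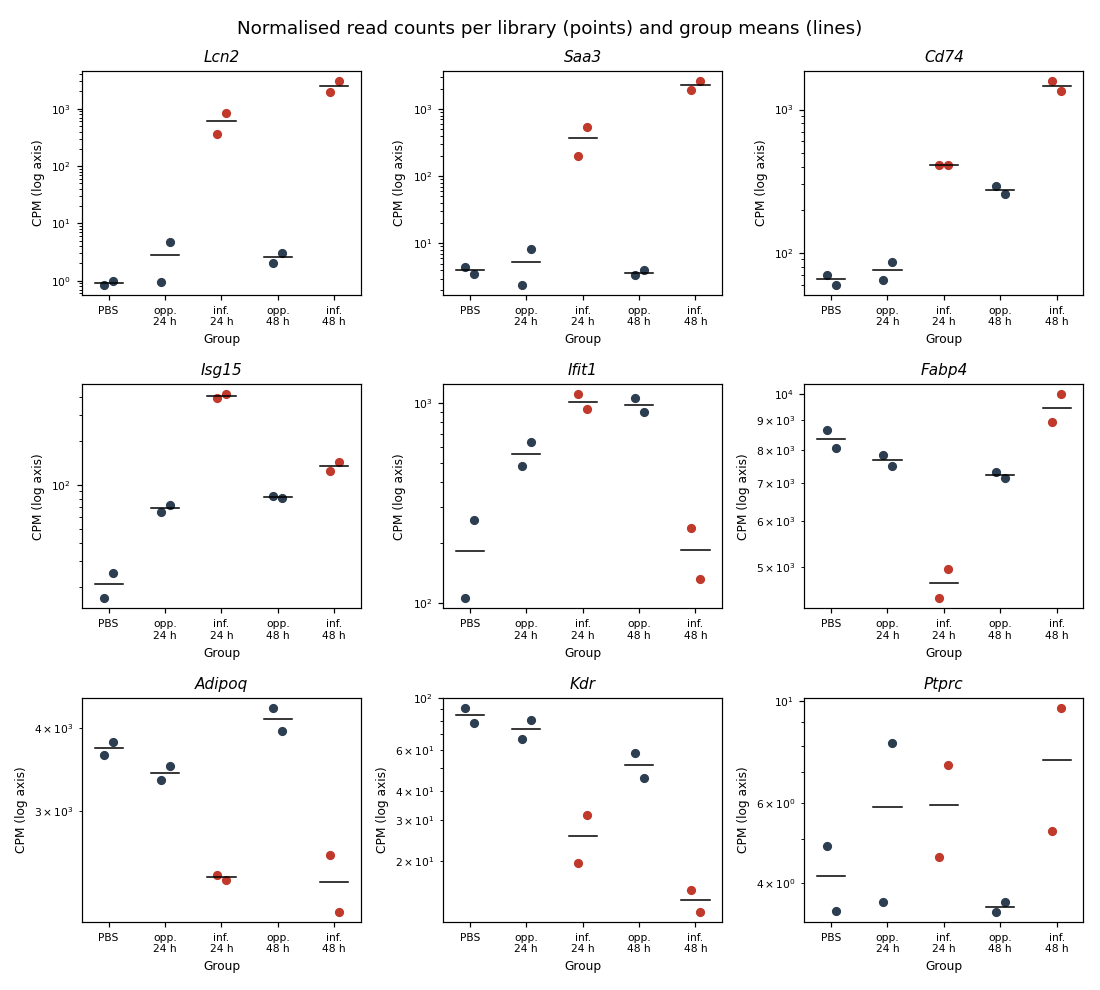
CPM (log axis) of named genes in each of the 10 libraries, with points for libraries and lines for the group means of 2 libraries. Lcn2 averaged 0.922 CPM in PBS mice and 2513 CPM in the infected leg at 48 h, and Adipoq 3724 and 2349 CPM.

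The infected leg was also compared between 48 h and 24 h. Class II genes rose further in 6 of 10 and fell in 1 (7 and 1 adjusted over the list alone; median 1.65), with H2-Eb1 at 2.57 ± 0.15, H2-Aa at 2.33 ± 0.15 and Cd74 at 1.83 ± 0.16 (SE, n = 2 per group). The class II list had adjusted p = 0.00309 (adjusted p = 0.134 with an estimated correlation). Adipocyte identity genes rose in 12 of 23 and fell in 4 (13 and 4 adjusted over the list alone; median 0.44), with Acvr1c at 1.56 ± 0.12, Fabp4 at 1.02 ± 0.15 and the adipocyte transcription factor Pparg at 0.83 ± 0.15. The adipocyte list had adjusted p = 0.000623 (adjusted p = 0.134 with an estimated correlation). Lipolysis genes rose in 10 of 20 (10 adjusted over the list alone; median 0.65), with the lactate receptor Hcar1 at 1.77 ± 0.13, Prkar2b at 1.70 ± 0.12 and Pde3b at 1.60 ± 0.13. The lipolysis list had adjusted p = 0.00309 (adjusted p = 0.134 with an estimated correlation). Its named genes here are regulators rather than lipases, so a rise of the list does not show a rise of lipolysis. Prkar2b had fallen from 591 ± 22.7 to 145 ± 13.3 CPM at 24 h and stood at 471 ± 24.4 CPM at 48 h (SD, n = 2). The endoplasmic reticulum gene Derl3 (ENSMUSG00000009092, chromosome 10, 75893413 to 75895941) rose by 3.60 ± 0.40, Clstn3 by 2.91 ± 0.23, the chemokine Ccl9 by 2.80 ± 0.33, Tnfsf13b by 2.42 ± 0.13, Col1a1 by 1.96 ± 0.31 and Dgat1 by 1.69 ± 0.14. Adipoq was at -0.02 and did not pass.

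Several interferon targets fell between 24 h and 48 h in the infected leg. Ifit2 went from 721 ± 255 to 97.8 ± 7.90 CPM (SD, n = 2; log2 fold change -2.88 ± 0.32, edgeR adjusted p = 0.000589). Ifit1 (-2.47 ± 0.43), Rsad2 (-2.18 ± 0.29), Ifit3 (-2.06 ± 0.27), Isg15 (-1.58 ± 0.15) and Gbp2 (-1.50 ± 0.22) fell too. In the type I list 21 of 35 fell, 3 rose and 11 did not pass (21 and 3 adjusted over the list alone; median -0.74; adjusted p = 0.0508). Cxcl9 was at -0.11 and did not pass. Ltbp4, a matrix protein (-3.08 ± 0.33), the smooth muscle actin Acta2 (-2.02 ± 0.24), Elovl6 (-1.92 ± 0.26), Thrsp (-1.80 ± 0.20), Fasn (-1.24 ± 0.23) and the small heat-shock gene Hspb1 (-1.29 ± 0.14) were lower. Blood endothelial markers had 10 of 14 lower (11 adjusted over the list alone; median -1.31; adjusted p = 0.0609).

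Lists called at 48 h against 24 h also included endoplasmic reticulum stress (7 of 18 higher, 1 lower), fatty acid oxidation (5 of 22 higher), immediate-early genes (9 of 24 lower, 1 higher), pericytes (4 of 9 lower, 1 higher), mitochondrially encoded mRNAs (6 of 13 lower) and the tricarboxylic acid cycle (11 of 22 lower, 1 higher). Stress genes had 9 higher and 1 lower adjusted over the list alone, oxidation 5 higher and 3 lower, immediate-early genes 13 lower and 1 higher, pericytes 5 lower and 1 higher, mitochondrially encoded mRNAs 6 lower and the tricarboxylic acid cycle 12 lower and 1 higher. Stress genes had an adjusted p = 0.0470 and the other 5 an adjusted p = 0.0405, and with an estimated correlation their adjusted p ran from 0.683 to 0.749. Each of these 6 calls was lost without infected-leg replicate 1 at 48 h (0.115 to 0.153) and without replicate 2 at 48 h (0.103 to 0.191), and some without infected-leg replicate 1 (0.0786 to 0.138) or 2 (0.0986 to 0.109) at 24 h. The stress call was also lost with RLE factors (0.0504). The adipocyte, lipolysis and class II lists held whichever library was left out. In all 2998 genes passed, 1441 higher and 1557 lower, and fry called 9 lists, 5 up and 4 down. Between 44.5 and 54.9% of the called genes were higher over the alternatives. Without infected-leg replicate 1 at 24 h the numbers were 1934 genes and 5 lists. Without replicate 2 at 48 h they were 1567 genes and 3 lists, and without replicate 1 at 48 h 3 lists were called.

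The local response itself was tested for a difference between 48 h and 24 h. The adipocyte list was less reduced at 48 h, with 7 of 23 genes higher in this contrast, 1 lower and 15 that did not pass (11 and 3 adjusted over the list alone; median 0.50; adjusted p = 0.00288, and adjusted p = 0.265 with an estimated correlation), including Acvr1c (1.55) and Nrg4 (1.24). Lipolysis had 6 of 20 higher (7 adjusted over the list alone; median 0.48), including Prkar2b (1.73) and Pde3b (1.68). Class I presentation had 10 of 21 lower and 1 higher (13 and 1 adjusted over the list alone; median -0.64), including Psmb10 (-1.54) and Tap2 (-1.32). Both had an adjusted p = 0.0235, and an adjusted p = 0.289 with an estimated correlation. In the opposite leg the class I list rose from a median of 0.795 at 24 h to 1.63 at 48 h, each against PBS mice. It was not called in the infected leg between the times. The rise in the opposite leg may therefore hold much of the smaller class I response. Among type I interferon-stimulated genes 19 of 35 were lower, 1 was higher and 15 did not pass (25 lower and 2 higher adjusted over the list alone; median -0.97; adjusted p = 0.0682), including Mx1 (-3.62 ± 0.47; SE, n = 2 per group; edgeR adjusted p = 0.00523) and Isg15 (-1.83). Collagens had 7 of 26 higher and 19 that did not pass (8 adjusted over the list alone; median 0.89; adjusted p = 0.137), with Col1a1 at 2.93. Against PBS mice the collagen list had a median of 0.344 in the opposite leg at 24 h and -0.573 at 48 h, neither called. The opposite leg may therefore hold part of this difference, though Col1a1 also rose in the infected leg between the times.

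The local response differed between the times in 946 genes, 499 higher and 447 lower at 48 h. The number was 463 without infected-leg replicate 1 at 24 h, 473 without infected-leg replicate 2 at 48 h, 571 without opposite-leg replicate 1 at 24 h, 378 and 303 without opposite-leg replicates 1 and 2 at 48 h, and 1596 with no filter. Without opposite-leg replicate 2 at 24 h, 305 were higher and 355 lower, and over all alternatives the share of higher genes ran from 43.9 to 59.2%. The adipocyte list held whichever library was left out. Class I and lipolysis lost their calls without infected-leg replicate 1 (0.106 for both) or 2 (0.0638 for both) at 24 h, infected-leg replicate 1 at 48 h (0.0868 and 0.0596), and opposite-leg replicate 1 (0.0637 for both) or 2 (0.0875 for both) at 48 h. Class I also lost it without infected-leg replicate 2 at 48 h (0.122), and lipolysis without opposite-leg replicate 2 at 24 h (0.0617).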

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

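Of the tests in this part, those of the difference between the local responses and of GC content and gene length were set before their results were seen, and the 6 others were chosen only after the result was seen. No test of a single library far from its group was made, since groups of 2 are too small for it.

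The local response differed between 48 h and 24 h in the test of the difference itself (edgeR, n = 2 per group) for 946 genes, for the lists of adipocyte identity (adjusted p = 0.00288), lipolysis (0.0235) and class I presentation (0.0235), and for the named genes that follow, given as log2 differences. These passed the test of the difference between the times. Negative values mean a lower infected-against-opposite ratio at 48 h. Of the 72 named genes called, 30 held whichever library was left out. With another filter, scaling, tool or choice of genes or libraries in the fit, the calls of Aldoa, Bgn, Dcn, Grk1, Idh3a, Ifit1, Lars2, Mir6236, Myd88, Nfkbie, Ogdh, Sesn2, Slc25a20 and Wfdc21 were lost in at least 1 of them (adjusted p = 0.0503 to 0.203).

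Named matrix and stromal genes with positive differences were Ssc5d at 3.98, Antxr1 at 3.52, Olfml3 at 3.49, Aebp1 at 3.28, Col1a1 at 2.93, Col1a2 at 2.28, Dcn at 1.99, Bgn at 1.97, Col6a3 at 1.86, Lum at 1.72 and Cd55 at 0.62. The collagen (adjusted p = 0.137) and preadipocyte (0.252) lists did not pass in this contrast, and opposite-leg replicate 2 at 24 h held more stromal counts than replicate 1 (Pdgfra 16.3 against 5.54 CPM, Dcn 157 against 81.2 CPM). Without that library the calls of Ssc5d (adjusted p = 0.0544), Aebp1 (0.0766), Bgn (0.145), Lum (0.1013) and Cd55 (0.0570) were lost. Against PBS mice the collagen list had a median of 0.344 in the opposite leg at 24 h and -0.573 at 48 h. The preadipocyte list had 0.954 and 0.129 there, so the opposite leg may hold part of the matrix and stromal differences. Fat and adipocyte genes with positive differences were Pck1 at 1.74, Prkar2b at 1.73, Pde3b at 1.68, Ffar2 at 1.56, Acvr1c at 1.55 and Kcnk3 at 1.38. Smaller ones were Acsl1 at 1.34, Hcar1 at 1.34, Nrg4 at 1.24, Fabp4 at 1.10, Pparg at 1.01, Hmgcs1 at 0.99 and Slc25a20 at 0.56. Negative ones were Thrsp at -2.11, Elovl6 at -2.00, Fasn at -1.57 and Cox8b at -1.40. In the lists of oxidative phosphorylation, the tricarboxylic acid cycle and glycolysis, which did not pass, the named genes were Pcx at -1.03, Uqcrc1 at -0.80, Ndufb8 at -0.74, Cyc1 at -0.73, Ogdh at -0.72, Ndufv1 at -0.71, Idh3b at -0.70 and Aldoa at -0.70, and Idh3a at 0.52.

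Of interferon and presentation genes, Mx1 was at -3.62, Ifit1 at -3.28, Ifit2 at -2.97, Rsad2 at -2.87, Isg15 at -1.83, Gbp2 at -1.59 and Gbp5 at -1.57. Smaller negative differences were those of Psmb10 at -1.54, Tapbpl at -1.48, Psmb9 at -1.47, Gbp3 at -1.45, H2-DMa at -1.45, H2-DMb1 at -1.43, Gbp7 at -1.36, Tap2 at -1.32 and Myd88 at -1.12. A negative difference need not be a fall in the infected leg. H2-DMa rose in both legs between the times, by the larger factor in the opposite leg, and its CPM values are given below. The class I list also rose in the opposite leg, with a median of 0.795 at 24 h and 1.63 at 48 h against PBS mice. Among the other named genes, Ccl9 was at 3.11, Wfdc21 at 2.47, Nfkbie at 1.67, Nr4a1 at 1.43, Zbtb46 at 1.32, Cxcl12 at 1.31, Sesn2 at 0.84, Dnajb9 at 0.82 and Scn7a at 0.64, and Mir6236 at -3.86, Grk1 at -3.42, Lars2 at -3.40, Ccl12 at -2.30, Il15 at -1.46, Egr2 at -1.40, Steap4 of the acute-phase list at -1.06, Btg2 at -1.03 and Atf3 at -1.02. Mir6236 and Lars2 are counted among the rRNA-like transcripts, a set picked in part for being high in the opposite leg at 48 h.

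Interferon-gamma, MHC and acute-phase genes were higher in the infected leg at 48 h than in PBS mice. Neutrophils as the source of Lcn2 were argued against by S100a8 and S100a9, abundant in those cells, which summed to at most 0.2564% of the CPM of Lcn2. The lower share of mitochondrially encoded mRNAs could raise all other genes by at most 0.162, against a median rise of 2.63 over 85 genes. Monocytes and macrophages as the source of the first 2 groups stay open, since their 19 markers went both ways (median 0.203, SD 2.84), and the difference of 2.439 from the median of 2.64 over 63 genes (permutation p = 2e-05, two-sided over genes, which are not independent) lies within that SD. T and NK cell markers (median 2.83; adjusted p = 0.00218, and adjusted p = 0.276 with an estimated correlation) and neutrophil markers (2.74; 0.0203, lost without PBS replicate 1 at 0.0932 or 2 at 0.0817, and adjusted p = 0.445 with an estimated correlation) rose beside these genes, so other cells and higher transcription in adipocytes both stay open.

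Type I interferon-stimulated genes had a smaller local response at 48 h than at 24 h in 19 of 35 genes. A rise in the opposite leg as the whole cause was argued against, since 21 of the 35 fell in the infected leg itself from 24 h to 48 h (median -0.739), though the opposite leg moved by a median of 0.458 and may hold part of it. After each library's trend with GC content and gene length was removed, 19 of the 19 genes were still called lower (median of the list -1.14) while 425 other genes changed their call, which argues against such a trend as the cause. A fall of the interferon response in time is a candidate explanation that was not tested further.

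Blood endothelial markers were lower in the infected leg at 48 h than in PBS mice, in 12 of 14 genes. A lower share of every cell type other than adipocytes as the whole cause was argued against, since the medians of 4 of 9 other lists lay apart from the endothelial one (-1.97) by more than both SDs. These were T and NK cells (2.83), neutrophils (2.74), skeletal muscle (0.10) and nerve (-0.16; permutation tests, two-sided over genes, adjusted p = 0.00504 to 0.00991), though some muscle and nerve markers had few counts. Neutrophils passed narrowly, with a difference of 4.717 against an SD of 4.707. The T and NK cell list holds the chemokine Ccl5. A lower share of vessel cells alone stays open, since pericyte (-1.39), red blood cell (-1.23) and the 3 lymphatic markers (-2.31) had negative medians too. Fewer endothelial cells in the preparation and lower expression in each cell cannot be told apart, since either could lower all 12 markers, and no biological explanation was tested.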

How the results depend on the processing

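Of the alternatives, leaving out rRNA-like transcripts was chosen only after the result was seen, and the others were planned. Over the named genes, 12590 comparisons with an alternative kept direction and side of the threshold, 121 gained and 986 lost the call, 0 calls turned round, and 105 differed in sign where neither setting made a call. Over the lists 2395 kept, 182 gained and 195 lost the call. Leaving out a library leaves 1 in its group, assumed to vary like the other groups. Depth sets a floor of 0.280 CPM for 3 counts in the shallowest library. Where no cause is named, the cause was not tested.

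With no filter, where more genes are tested, 738 genes were called in the opposite leg at 24 h, 1608 at 48 h, and 1596 for the difference between the local responses. DESeq2 called 359 in the opposite leg at 24 h, and the fit of only the libraries compared 1749 in the opposite leg at 48 h. With 1 library left out, calls ran from 2182 to 2611 (local response at 24 h), 1610 to 2752 (48 h), 70 to 432 (opposite leg at 24 h), 325 to 510 (48 h), 2687 to 3291 (infected leg at 24 h against PBS mice), 2877 to 3862 (48 h), 1567 to 2419 (infected leg between times) and 303 to 873 (difference of the local responses). The overlap of the local responses was 661 genes at a threshold of 0.01 against 1450.

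Lists called with an estimated correlation numbered 1, 0, 4, 6, 0 and 0 in the local responses at 24 h and 48 h, the infected leg against PBS mice at 24 h and 48 h, the infected leg between times and the difference of the local responses. Of the opposite leg's lists, 3 and 4 held. With a preset correlation 13 and 11 were called in the opposite leg at 24 h and 48 h, and 14 and 14 in the last 2 comparisons. Fry for change in either direction called 28 and 32 in the local responses, 11 and 26 in the opposite leg, 29 and 32 in the infected leg against PBS mice, 31 between times and 24 for the difference. With 1 library left out, lists ran from 6 to 12 (local response at 48 h), 2 to 6 (opposite leg at 24 h), 3 to 6 (infected leg between times) and 1 to 4 (difference). With all libraries kept, RLE factors ended the list calls of the cell cycle (0.0519, infected leg at 48 h against PBS mice) and endoplasmic reticulum stress (0.0504, infected leg between times). Leaving out rRNA-like transcripts ended none. Apart from the replicate block given below, the other filters, gene sets and fits, and DESeq2, were not run on the lists.

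The replicate numbers are shared between groups, and the labels do not say that they mark animals. With the number as a replicate block, 3507, 3205, 273, 1078, 4252, 4556, 3102 and 1035 genes were called in the 8 comparisons, against 3430, 3148, 213, 925, 4179, 4475, 2998 and 946, and 5 lists against 9 for the infected leg between times. The calls lost there were endoplasmic reticulum stress (0.0695), immediate-early genes, pericytes and mitochondrially encoded mRNAs (0.0592 for each of these last). The block also left uncalled the collagen list in the local response at 48 h (0.0743) and mitochondrially encoded mRNAs in the infected leg at 24 h against PBS mice (0.0521). With a replicate block by infected animal 4264 and 4021 were called in the local responses and 1753 for their difference. Genes it called higher that the main fit did not included Ptprc (0.00863) and Pparg (0.0463) at 48 h and Ifit1 (0.00459) at 24 h. For the difference it left Col1a2 uncalled (0.0685), and the block by number alone left Lum uncalled (0.0644). Deviations of same-numbered libraries from their group means correlated across genes at 0.317 (legs at 24 h), 0.117 (legs at 48 h), 0.138 (infected legs), -0.153 (opposite legs), -0.106 (infected leg at 24 h with opposite leg at 48 h) and -0.0449 to 0.0298 for the others.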

Other observations

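This part reports no test, so no tests were chosen only after the result was seen, but its genes were chosen after their values were seen. Lpl, which frees fatty acids from lipoproteins, was at 10291 ± 164 CPM in PBS mice (SD, n = 2). It was at 6814 ± 277 and 6804 ± 238 CPM in the opposite leg at 24 h and 48 h, and at 2476 ± 241 and 3368 ± 33.1 CPM in the infected leg (SD, n = 2). Scd1 was at 27201 ± 1478 CPM in PBS mice, 24784 ± 2447 and 19006 ± 2619 CPM in the opposite leg and 23957 ± 1874 and 10510 ± 336 CPM in the infected leg (SD, n = 2). Fabp4, low in the infected leg at 24 h (4676 ± 382 CPM), was at 9453 ± 751 CPM at 48 h (SD, n = 2), while Adipoq was at 2389 ± 31.4 and 2349 ± 323 CPM.

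Ly6a, a surface gene of stromal cells that interferons also induce, was at 64.7 ± 1.32 CPM in PBS mice, 238 ± 10.9 and 666 ± 64.5 CPM in the opposite leg and 1311 ± 248 and 4250 ± 675 CPM in the infected leg at 24 h and 48 h (SD, n = 2). The class II gene H2-DMa was at 6.33 ± 1.60 and 48.5 ± 1.20 CPM in the opposite leg and 46.2 ± 2.90 and 130 ± 20.6 CPM in the infected leg at these times (SD, n = 2). Ifit1 was at 558 ± 108 and 977 ± 109 CPM in the opposite leg and at 1016 ± 124 and 183 ± 73.5 CPM in the infected leg, beside 182 ± 109 CPM in PBS mice (SD, n = 2).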
